A study of Mus musculus with 15 samples.

How the data were processed

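Single mouse oocytes at the GV and MII stages were sequenced with MATQ-seq, per the labels. GV oocytes were collected 44 h after 7 IU of pregnant mare serum gonadotropin. MII oocytes came from mice given the same dose and, about 48 h later, 7 IU of human chorionic gonadotropin. They were taken from the oviducts after a further 20 h and freed of cumulus cells with 300 IU/mL hyaluronidase. Per the labels' protocols, cDNA was made in droplets, amplified by 28 cycles of PCR and sheared to 300 bp before the sequencing libraries were built. The labels name neither the mice nor their strain.

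The deposited values are whole-number counts per Ensembl gene ID, 1 file per oocyte, per the file headers and the values, which start at 1 and sum to different totals. The file names call them exon counts. The submitters' processing notes name cutadapt 4.0, STAR 2.7.10a and the build GRCm39. The counting tool, its gene annotation, its use of strand, its treatment of reads that match several genes and any molecular identifiers are not given in the sources used here. Without a stated strand, reads of a gene and an antisense or overlapping partner cannot be told apart, and genes with near-identical copies may share reads. A gene absent from a file was taken as 0 counts.

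Samples were grouped by the stage in their labels, 9 GV and 6 MII oocytes. The column headers of the files differ: 6 GV files (GV1 to GV6) have headers that begin with Y, 3 (GV7 to GV9) have headers that begin with E, and the 6 MII files share 1 header and are sorted by gene ID. The main values pool all GV files with no adjustment for these sets, and each set of GV files alone was used as an alternative. What the headers stand for is not given in the sources used here. The 51 pairs of oocytes of 1 stage were compared by a chi-square of their counts over genes, and the lowest value per degree of freedom was 8.05, so no pair agreed within sampling noise.

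Gene symbols came from the GENCODE M21 annotation of the older build GRCm38, used for names, biotypes and transcript lengths and for no coordinates. Of 28785 gene IDs, 28402 (98.7%) had a symbol. These held 91.1% of all counts, and 99.6% with the unnamed feature ENSMUSG00000119584 left out. Of 542 entries in 26 gene lists, 495 were matched by symbol and 47 by RefSeq accession. The lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The lists were 22 pathways and complexes and 4 lists of markers of other cell types (cumulus and granulosa, theca and stroma, blood and immune, oviduct epithelium).

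Each stage counts as 1 sample, since its oocytes are cells with no mouse named. No p-value, standard error or test-based count of genes was therefore made, and no gene is called changed. Counts were summed over the oocytes of a stage and given as CPM, counts scaled to a common total. The log2 ratio MII/GV was taken after adding 0.5 to each summed count. A gene was measured with at least 5 CPM in the higher stage. Because the median measured gene had a log2 ratio of −0.98, ratios were given relative to it. Sums have exact Poisson and shares exact binomial (Clopper-Pearson) 95% intervals. For the 52 named genes with at least 100 counts in each stage, the Poisson intervals reached at most 15.2% from the value in GV and 20.9% in MII. A gene with 0 counts in MII was compared with a floor of 3 counts over the stage, 0.311 CPM. PCR reads are not independent molecules, so intervals and floors cover counting error only.

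The spread between oocytes of a gene was taken from log2(CPM + 1) minus that of the oocyte's median measured gene. The SDs of both stages were combined as the root of the sum of their squares. For a list, the median over its measured genes was used per oocyte. The spread describes these oocytes and is no error of a mean. A list's median was set among 10000 random lists of the same size drawn from 20 bins of level, as a description of these libraries. Named genes were protein-coding genes with the 12 lowest and 12 highest ratios, with at least 20 CPM in the higher stage and medians over oocytes at least 2-fold apart in the same direction (predicted genes and clone names left out). For each pathway or complex the most abundant member and those with the lowest and highest ratio were named, and for each marker list the most abundant member.

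For genes detected, correlations and variation between oocytes, each oocyte was thinned without replacement to 808641 counts, the total of the shallowest. The alternatives were the mean or median of CPM over oocytes in place of sums, thinning before summing, edgeR's TMM factor, DESeq2's median-of-ratios factor, totals without mitochondrial genes or without the 50 genes with most counts, other filters on level, and leaving out each oocyte. Added after seeing the data were totals without the unnamed feature, ratios relative to the median gene, each set of GV files alone, and leaving out GV1 and GV2 or MII5 and MII6. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.

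The ratios were tested on simulated data for GV against MII, with counts drawn for the real genes and oocyte totals, a spread between oocytes of 1 dispersion (0.2) for all genes, and 200 genes changed: 50 were made 8-fold lower (median relative ratio −3.09), 50 were made 4-fold lower (−2.05), 50 4-fold higher (1.97) and 50 8-fold higher (3.03). All 50 of each size came out in the right direction. These medians and directions cover all 200 changed genes, also those that failed the filter on level. The filter was passed by 10134 genes, 197 of those changed and 9937 unchanged. Of the unchanged genes 0 were 4-fold apart. The simulation leaves out the unnamed feature and spreads each oocyte's full total over the other genes. Genes in simulated MII oocytes therefore hold more counts than the real ones. The simulation also holds no difference between sets of files, and in the real data 922 and 603 genes were at least 4-fold lower or higher between the 2 sets of GV files, so it gives no rate of chance differences for these oocytes.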

Results

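Transcriptomes of single mouse oocytes were measured at 2 stages of maturation with MATQ-seq, a single-cell method that amplifies total RNA. The germinal vesicle (GV) stage is the fully grown oocyte arrested in meiotic prophase, and the MII stage is the mature egg arrested in metaphase of the second meiotic division. The set held 9 GV oocytes and 6 MII oocytes, 1 oocyte per library. The single comparison in the design, GV against MII, asks how the oocyte transcriptome differs between these stages. Total counts were 3687610 to 7103063 per GV oocyte and 808641 to 2348281 per MII oocyte. The labels name no mouse, so the oocytes of a stage were treated as cells of 1 sample, no test was made, and all differences below are described by size beside the spread between oocytes.

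A single feature took a large part of the MII counts. This feature, ENSMUSG00000119584 in the files, has no symbol in the gene tables used here and was singled out after its values were seen. It took 15.7% to 61.2% of the counts of each MII oocyte and 3.43% to 11.2% in GV7, GV8 and GV9. It had 0 counts in GV1 to GV6, for which the exact binomial 95% limit was 8.65e-05% in the shallowest of them. The exact binomial 95% intervals of all shares given for single oocytes reached at most 0.103 percentage points from the value. The files of GV1 to GV6 and of GV7 to GV9 also carry different kinds of column header (Y and E), so values against 1 or both sets are given below for many lists and genes that depend on the set. All 6 MII files carry another header, which means that stage and file set cannot be told apart.

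**Figure D1:**
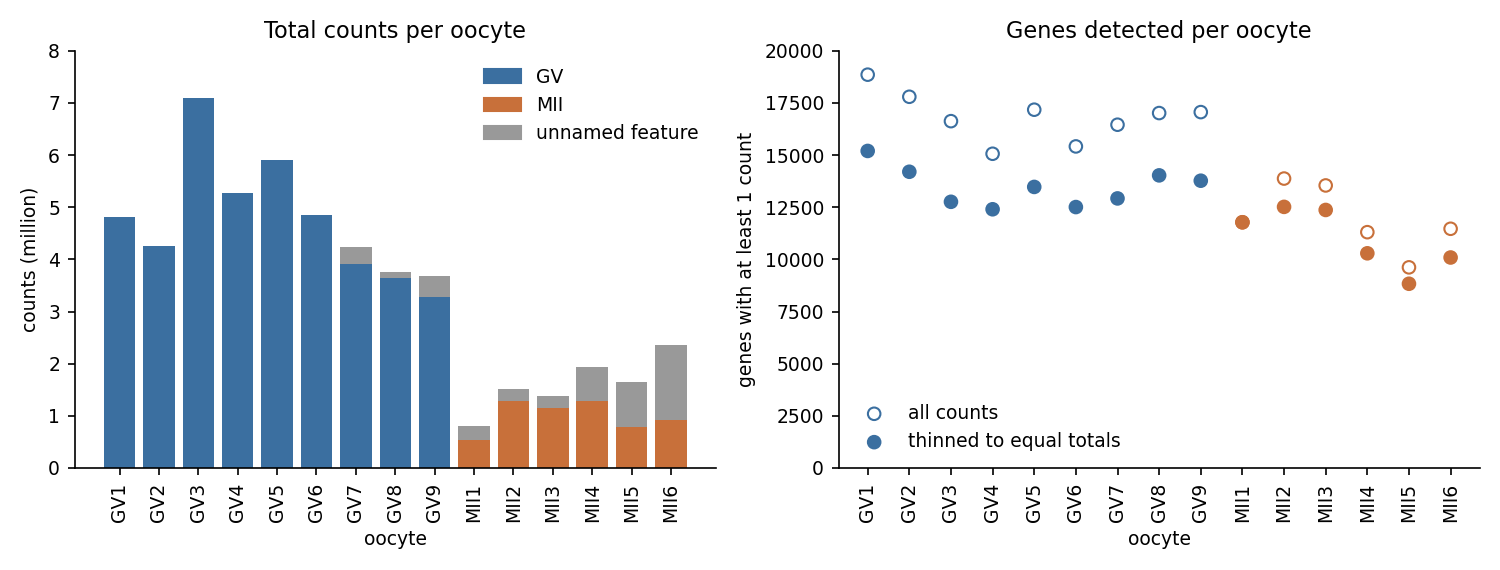
Left, total counts per oocyte, with the part taken by the unnamed feature in grey; right, genes with at least 1 count per oocyte, from all counts (open circles) and after thinning to equal totals (filled circles), with GV in blue and MII in orange. The feature takes up to 61.2% of an MII library, and at equal totals the GV oocytes span 12401 to 15197 genes and the MII oocytes 8830 to 12516.

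Most transcripts had a lower share of the counts in MII. Of 10090 measured genes, 1529 were at least 4-fold lower and 51 at least 4-fold higher in MII in CPM (counts scaled to a common total), so that 96.8% of the genes this far apart were lower. This split depends on the scaling, since the median measured gene itself stood at a log2 ratio MII/GV of −0.98. Relative to the median measured gene, 657 genes were at least 4-fold lower and 198 at least 4-fold higher, a split of 76.8% lower. The split was 716 and 161 genes with TMM scaling (81.6% lower) and 688 and 180 with median-of-ratios scaling (79.3% lower). Ratios below are log2 MII/GV relative to this median gene, and a gene or list with a ratio between 0 and 0.98 is therefore lower in MII on the scale of total counts. That direction depends on the scaling, since the median gene stood at −0.31 with totals that leave out the feature, −0.11 with TMM and −0.063 with median-of-ratios scaling. The number after ± is the spread between oocytes, the SDs of 9 GV and 6 MII oocytes combined. It comes from levels per oocyte, not from the summed counts behind the ratio. A ratio larger or smaller than its spread is therefore a rough guide only, above all for genes near 0 counts. Without GV1 and GV2 the count of lower genes relative to the median gene was 423, and against GV7 to GV9 alone that of higher genes was 675. By the same measure many genes also differed between the 2 sets of GV files. Of 10763 genes measured there, 922 were at least 4-fold lower and 603 at least 4-fold higher in GV7 to GV9. These numbers are not like for like with those of the stages, which pool both sets and hold more oocytes. Lower and higher genes in MII numbered 742 and 223 against GV1 to GV6 alone, and 783 and 675 against GV7 to GV9 alone. Of 83 named genes, 47 had a ratio that moved over 1.5-fold when 1 set of GV files was used alone, and 28 when 1 oocyte was left out.

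The genes furthest below the median gene had counts in GV libraries and few or none in MII. Relative to the median gene the 12 lowest ratios ran from −8.99 to −4.90. The folds and bounds in this paragraph are instead in CPM, with the unnamed feature counted. They would be smaller relative to the median gene or with the feature left out. Pxdn (peroxidasin, an extracellular matrix enzyme), Ccnd2 (cyclin D2), Inha (the inhibin alpha subunit), Pknox2 (a homeobox factor), Alpk3 (a kinase) and Tnc (tenascin C, a matrix protein) had 0 counts in every MII oocyte. Against a floor of 3 counts over the stage, in CPM, Pxdn was at least 168-fold lower in MII, Ccnd2 at least 160-fold, Inha at least 127-fold, Pknox2 at least 84.9-fold, Alpk3 at least 66.8-fold and Tnc at least 65.4-fold. These bounds differed between the sets. Against GV1 to GV6 and against GV7 to GV9 they were 1.79 and 624 for Pxdn (101 without GV7) and 161 and 36.0 for Inha. Ccnd2 was at least 214-fold lower against GV1 to GV6 and had 40 counts in GV7 to GV9. The bounds were 43.1 and 200.2 for Pknox2, 89.9 and 3.29 for Alpk3 and 25.9 and 174 for Tnc. Dclk1, Zeb2 and Cplx2 had 1 MII count each, in a single oocyte. Their GV levels in CPM were 337-fold (95% counting interval 60.4 to 13318), 283-fold (50.7 to 11178) and 233-fold (41.7 to 9202) above MII. For Dclk1 this was 44.6-fold (7.87 to 1771) in GV1 to GV6 and 1143-fold (205 to 45159) in GV7 to GV9. For Zeb2 it was 19.8-fold (3.22 to 813) in GV7 to GV9, 181-fold (32.3 to 7150) without GV2 and 71.3-fold (12.7 to 2829) without GV1 and GV2. For Cplx2 it was 116-fold (20.8 to 4602) without GV1, and its 17 counts in GV7 to GV9 gave an interval of 2.19 to 585. Pafah1b3, a subunit of the platelet-activating factor acetylhydrolase, was 98.8-fold above (27.3 to 817), the tensin gene Tns1 69.0-fold (23.5 to 335) and the tubulin carboxypeptidase gene Agbl2 71.1-fold (36.0 to 165). Tns1 was 28.4-fold above (9.64 to 138) without GV1 and 7.96-fold (2.47 to 40.8) in GV7 to GV9, and the ratio of Agbl2 was −5.84 without MII1. GV oocytes were far from uniform in these genes. Ccnd2, Inha, Alpk3, Cplx2 and Tns1 were highest in GV1, the oocyte with the highest share of cumulus and granulosa cell markers (290 CPM), and Inha is itself such a marker. However, Alpk3 was nearly as high in GV4 (48.2 CPM, 49.1 in GV1), where Inha was at 0. GV1 also held 20 of 40 genes restricted to other organs. The source of these mRNAs is therefore not settled here. Mean levels were 64.4 ± 99.2 CPM for Pxdn and 46.1 ± 51.6 CPM for Ccnd2 (SD, n = 9). Of the 12 genes with the lowest ratios only 2 had GV and MII ranges in CPM that did not overlap. Pxdn was at 139 to 245 CPM in GV7 to GV9 and at 0 to 2.29 CPM in GV1 to GV6, and Agbl2 at 174 to 267 CPM against 0 to 10.1 CPM; against GV1 to GV6 alone the ratio of Agbl2 was 0.049.

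The genes furthest above the median gene in MII had ratios of 2.91 to 3.90. These ratios are relative to the median gene and are larger than the same ratios in CPM. Rln3, which encodes the peptide hormone relaxin-3, was at 24.6 ± 25.2 CPM in GV (SD, n = 9) and 180 ± 115 CPM in MII (SD, n = 6), a ratio of 3.90 ± 1.96. Crabp2, a retinoic acid-binding protein, was at 37.9 ± 27.0 and 192 ± 71.9 CPM (3.26 ± 1.03). Prr5, a subunit of the mTORC2 kinase complex, was at 73.7 ± 27.5 and 295 ± 54.3 CPM (2.96 ± 0.82), and Nfu1, an iron-sulfur cluster scaffold of mitochondria, at 135 ± 87.9 and 539 ± 286 CPM (2.93 ± 1.38). The protein phosphatase 1 inhibitor Ppp1r11 had a ratio of 3.43 ± 1.59, the death receptor adaptor Fadd 2.96 ± 1.27 and the SMN complex member Gemin7 2.91 ± 2.19. The others of these 12 genes were Aspscr1 (3.53 ± 1.86), Apol6 (3.20 ± 2.15), Dpep3 (3.04 ± 2.11), Rapsn (3.04 ± 1.96) and Sfta2 (3.01 ± 1.55). Without MII5 the ratio was 2.45 for Dpep3, 2.44 for Rapsn, 2.35 for Sfta2 and 2.36 for Fadd, and without MII5 and MII6 the 12 ratios ran from 1.81 for Gemin7 to 3.23 for Rln3. Against GV1 to GV6 and against GV7 to GV9 the ratios were 3.53 and 6.22 for Rln3, 2.66 and 5.49 for Rapsn, 2.71 and 4.44 for Sfta2 and 2.61 and 4.49 for Nfu1. With all oocytes the 12 ratios exceeded the spread between oocytes. For 4 of the 12 (Crabp2, Fadd, Prr5 and Nfu1) the CPM ranges of GV and MII oocytes did not overlap. In levels relative to the median gene, the ranges of Rln3, Aspscr1, Ppp1r11 and Sfta2 did not overlap either.

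Transcripts of the egg coat and of other secreted oocyte factors were lower in MII. The relative level of this list per oocyte averaged 4.54 in GV (3.20 to 5.59) and 2.91 in MII (2.26 to 3.38). The ranges of the stages thus overlapped. The median ratio of the 10 measured genes was −0.87 ± 0.93, and 3 genes were at least 2-fold lower and 1 at least 2-fold higher. Zp2, a zona pellucida glycoprotein, was at 1024 CPM in the summed GV counts (exact Poisson 95% interval 1014 to 1033) and 58.4 CPM in MII (53.6 to 63.4), a ratio of −3.15 ± 1.08 (−4.21 against GV7 to GV9). It was lower in every MII oocyte than in any GV oocyte. Zp3, the most abundant member, was at 7570 and 2013 CPM (−0.93 ± 1.09); its ratio was −1.20 against GV1 to GV6 and 0.19 against GV7 to GV9. The secreted oocyte protein gene Oosp1 had a ratio of 1.10 ± 2.14 against all GV oocytes, 1.96 against GV1 to GV6 and −0.19 against GV7 to GV9. The list's summed share was 17605 CPM in GV (95% interval 17566 to 17644) and 5653 CPM in MII (5606 to 5701). Its median lay at percentile 0 of 10000 random lists of equal size and level.

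Members of the subcortical maternal complex, a protein assembly of the egg cortex needed by the early embryo, went in opposite directions. The median of 8 genes was −0.80 ± 0.70 (percentile 0.01), with 3 at least 2-fold lower and 1 at least 2-fold higher. Khdc3 was at 61.2 CPM in GV and 1.45 CPM in MII (14 counts), a ratio of −4.36 ± 1.27. Zbed3, the most abundant member, was at 11982 and 13310 CPM (1.13 ± 0.81). The list median was −0.18 against GV1 to GV6 and −1.65 against GV7 to GV9. Oocyte transcription factors had a median of −0.46 ± 0.58 over 8 genes (percentile 1.35; mean −0.02), with 1 at least 2-fold lower and 2 higher, and the median was 1.48 against GV7 to GV9. In that list Obox1 had a ratio of −1.02 ± 0.56, Obox2 −0.81 ± 1.54 (1.75 against GV7 to GV9) and Sohlh2 1.40 ± 2.02. The Obox genes are near-identical copies, and their separate counts are uncertain.

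**Figure D2:**
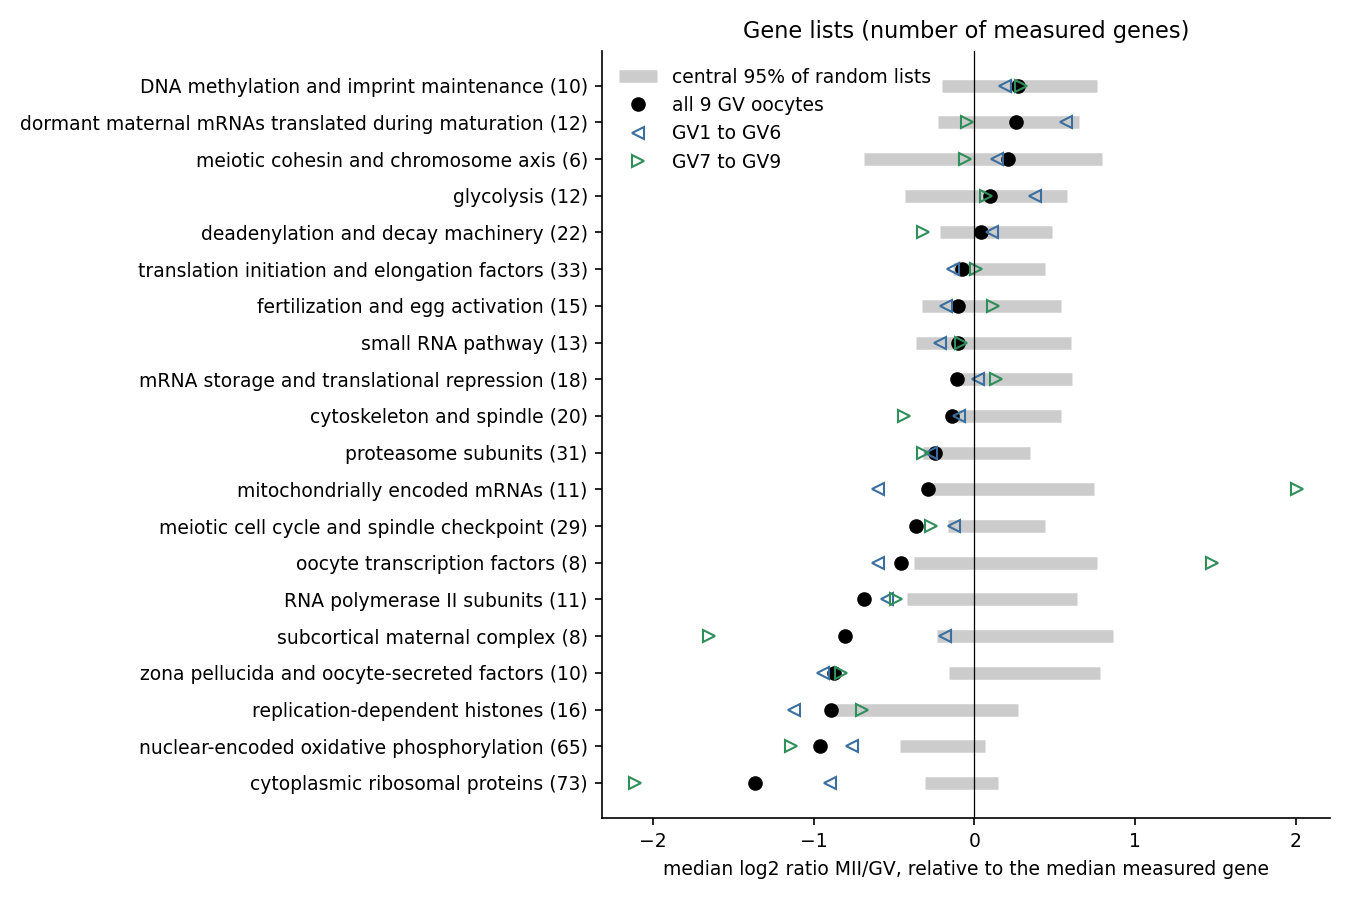
Median log2 ratio MII/GV of each gene list with at least 5 measured genes, relative to the median measured gene, for all GV oocytes (filled circles), GV1 to GV6 (left-pointing triangles) and GV7 to GV9 (right-pointing triangles); grey bars span the central 95% of random lists of the same size and level. Ribosomal protein genes lie lowest at −1.37, and the mitochondrially encoded mRNAs move from −0.60 to 2.01 between the 2 sets of GV oocytes.

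Ribosomal protein mRNAs had the lowest median among lists of 5 or more measured genes. Of 73 measured genes, 44 were at least 2-fold lower and 4 at least 2-fold higher in MII, with a median of −1.37 ± 1.05 (percentile 0). Rps2, the most abundant, was at 465 ± 177 CPM in GV (SD, n = 9) and 71.1 ± 27.1 CPM in MII (SD, n = 6), a ratio of −1.71 ± 1.12. Rps29 had 425 counts in GV and 0 in MII, at least 31.1-fold lower in CPM (26.0 against GV1 to GV6 and 45.0 against GV7 to GV9), while Rpl13a had a ratio of 1.76 ± 1.33. The oocytes of the stages overlapped for this list: its relative level per oocyte was −1.40 to 0.79 in GV and −2.35 to −0.67 in MII. The list median was −0.90 against GV1 to GV6 and −2.11 against GV7 to GV9. Ribosomal protein genes have many processed pseudogenes, and how reads shared with them were counted is not given in the sources used here.

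Nuclear-encoded genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were lower too, within the spread between oocytes. The median of 65 genes was −0.96 ± 1.07 (percentile 0), with 30 at least 2-fold lower and 5 at least 2-fold higher. It was −0.74 without GV4, and −0.50 in the alternative nearest to 0. The oocytes of the stages overlapped for this list too. Its relative level per oocyte was −1.63 to 0.23 in GV (mean −0.91) and −2.55 to −0.40 in MII (mean −1.47). Ndufc1, a complex I subunit, had 310 counts in GV and 1 in MII (in MII1), 68.0-fold lower in CPM (95% counting interval 12.1 to 2695), and 32.1-fold (5.44 to 1301) against GV7 to GV9. The list's most abundant gene went the other way: Sdhc of complex II was at 97.9 and 177 CPM (1.84 ± 1.03), and Cox6a1 of complex IV at 42.6 and 116 CPM (2.43 ± 1.72; 1.40 without MII5 and MII6). The 11 mitochondrially encoded mRNAs had a median of −0.29 ± 2.08 (percentile 2.02), which was 0.98 without GV2, 1.02 without GV1 and GV2, −0.60 against GV1 to GV6 and 2.01 against GV7 to GV9. In this list mt-Nd2 was at −0.57 ± 2.74, mt-Nd4 at −1.12 ± 2.00 and mt-Co3 at 1.55 ± 1.76 (3.54 against GV7 to GV9), and the first 2 were 2.18 and 1.03 against GV7 to GV9 and 1.10 and 0.20 without GV2. Glycolysis genes had a median of 0.10 ± 0.94 over 12 genes (percentile 54.9), lower in MII on the scale of total counts and with TMM, and 0.036 with median-of-ratios scaling. It had no fixed sign, with 0.38 against GV1 to GV6, −0.01 without GV2, −0.12 without MII5, −0.09 without MII6 and −0.44 without both MII5 and MII6. The list's most abundant gene, the lactate dehydrogenase gene Ldhb, was at 0.06 ± 0.87 (−0.21 without MII6, −0.50 without MII5 and MII6), Pgam1 at −1.05 ± 2.59 (−3.23 without MII6, −2.99 without MII5 and MII6, −1.87 against GV7 to GV9) and Pfkl at 1.36 ± 2.05 (2.39 against GV7 to GV9).

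Subunits of RNA polymerase II had a median of −0.68 ± 0.80 over 11 genes (percentile 0.32), with 3 at least 2-fold lower and 0 at least 2-fold higher. The list median was −0.29 without GV4. The list's relative level per oocyte differed little, with means of 0.63 in GV (−0.07 to 1.32) and 0.44 in MII (−0.43 to 1.32). Polr2k had 1359 counts in GV and 25 in MII (−2.57 ± 1.24; −1.94 without GV4, −1.27 against GV7 to GV9), Polr2c had a ratio of −0.68 ± 1.11 (0.88 against GV7 to GV9) and Polr2f 0.44 ± 1.31 (1.03 without GV4, 1.75 against GV7 to GV9, −0.07 without MII5 and MII6), lower in MII on the scale of total counts but higher without the feature (0.13) or with TMM (0.33). Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median of −0.89 ± 1.13 over 16 genes (percentile 2.18). Of these, 7 were at least 2-fold lower and 1 at least 2-fold higher. H1f1 had a ratio of −0.57 ± 1.58 (1.47 against GV7 to GV9, 0.05 without GV4) and H4c3 1.35 ± 2.19 (2.39 against GV1 to GV6, −0.05 against GV7 to GV9), and H2bc7 had 263 counts in GV and 0 in MII, at least 19.2-fold lower in CPM (11.1 without GV2 and 2.86 without GV1 and GV2); GV1 and GV2 held it at 22.1 and 29.5 CPM, and GV7 to GV9 had 0 counts of it too. Histone copies share sequence, so single members are uncertain.

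Genes of the meiotic cell cycle and spindle checkpoint stayed close to the median gene. The median of 29 genes was −0.36 ± 0.59 (percentile 0.07), and 25 of the 29 lay within 2-fold. Plk1, the polo-like kinase of meiotic divisions, was at 1035 ± 106 CPM in GV (SD, n = 9) and 1176 ± 322 CPM in MII (SD, n = 6), a ratio of 1.16 ± 0.39. The checkpoint kinase gene Bub1 had a ratio of −1.08 ± 1.55 and Cdk1, the kinase of meiotic resumption, 1.71 ± 1.32 (0.90 against GV7 to GV9). Dormant maternal mRNAs, stored in GV oocytes and translated during maturation, had a median of 0.26 ± 0.72 over 12 genes (percentile 60.5), and −0.08 without MII2 and −0.05 against GV7 to GV9. It was lower in MII on the scale of total counts and without the feature (−0.06), but higher with TMM (0.14). Of these, 11 lay within 2-fold. Among them the cyclin B1 gene Ccnb1 was at 282 and 67.5 CPM (−1.08 ± 0.64). Btg4, an adaptor for deadenylation of maternal mRNA, was at 243 CPM in both stages (0.98 ± 0.64), and the decapping activator gene Dcp1a was at 2583 and 2192 CPM (0.75 ± 0.76), lower in MII on the scale of total counts but higher without the feature (0.43) or with TMM (0.63). The deadenylation and decay machinery had a median of 0.04 ± 0.59 (percentile 31.3; mean −0.14), with 20 of 22 genes within 2-fold. Its sign was not fixed: the median was at or below −0.00 without GV3, GV6, MII2 (−0.18) or MII3, and −0.32 against GV7 to GV9. Its lowest member was the uridylyl transferase gene Tut4 with 236 counts in GV and 1 in MII (in MII2), 51.8-fold lower in CPM (9.20 to 2054).

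**Figure D3:**
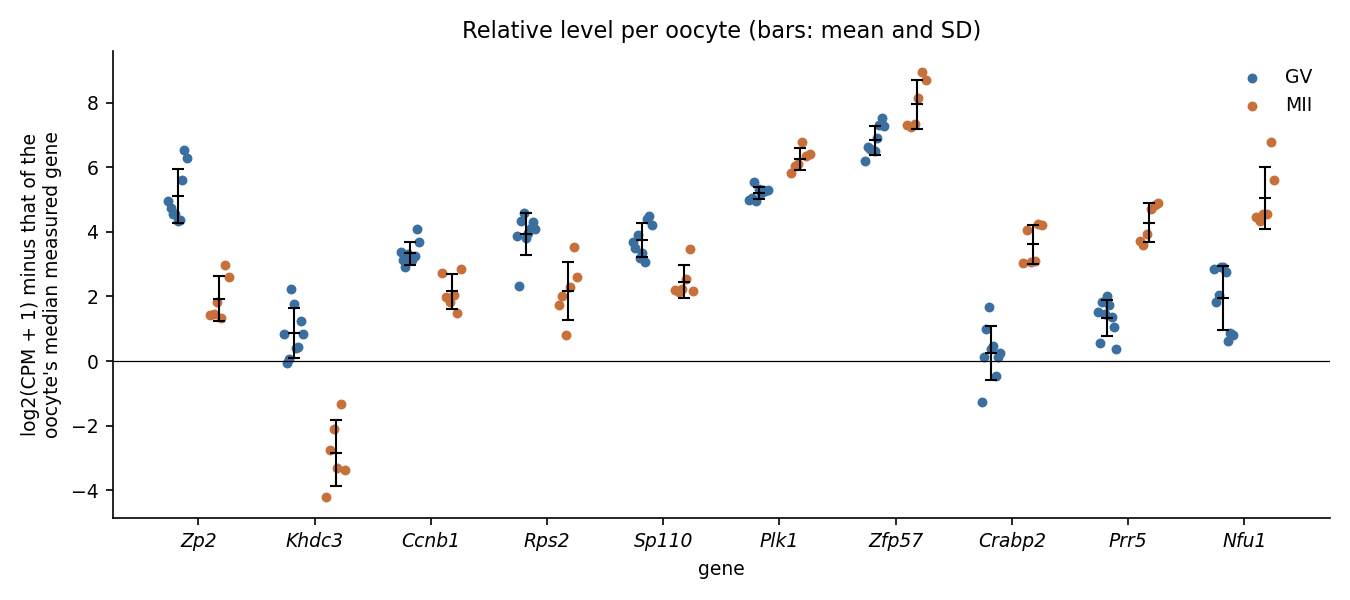
Relative level of 10 named genes in each oocyte, as log2(CPM + 1) minus that of the oocyte's median measured gene, for GV (blue) and MII (orange), with bars for the mean and SD. Zp2, Khdc3 and, narrowly, Ccnb1 lie lower in all 6 MII oocytes than in any of the 9 GV oocytes, and Plk1, Crabp2, Prr5 and Nfu1 lie higher.

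Translation and storage factors lay near the median gene. Initiation and elongation factors had a median of −0.08 ± 0.38 over 33 genes (percentile 5.99), and 0.01 against GV7 to GV9, with 8 at least 2-fold lower and 2 at least 2-fold higher. Eef2 had a ratio of 0.46 ± 0.96, lower in MII on the scale of total counts but higher without the feature (0.15) or with TMM (0.35), and 1.40 relative to the median gene against GV7 to GV9. Eif6, which keeps ribosomal subunits apart, was at 1.44 ± 1.18 (0.71 without MII5 and MII6), and Eef1g had 485 counts in GV and 2 in MII (both in MII1), 53.2-fold lower in CPM (14.6 to 441), and 28.4-fold (7.57 to 239) against GV7 to GV9. Genes of mRNA storage and translational repression had a median of −0.11 ± 0.38 over 18 genes (percentile 3.34). Its sign was not fixed, with 0.02 against GV1 to GV6, 0.14 against GV7 to GV9, 0.01 without MII6 and 0.09 without MII5 and MII6. The oocyte cap-binding protein gene Eif4e1b was at 2857 and 1223 CPM (−0.24 ± 1.11; 0.17 against GV7 to GV9, −0.94 without MII5 and MII6). Ybx2, an RNA-binding protein that masks maternal mRNA, was at 1324 and 1488 CPM (1.15 ± 1.53; 1.97 against GV7 to GV9, 0.19 without MII5 and MII6), and the m6A reader gene Ythdf2 at 58.2 and 7.27 CPM (−2.01 ± 1.09; −1.42 without GV1 and GV2). The small RNA pathway had a median of −0.10 ± 0.47 over 13 genes (percentile 17.9), 0.01 without GV6 and 0.03 without MII5 and MII6. There Dicer1 was at 1192 and 824 CPM (0.45 ± 1.06), higher in MII without the feature (0.14), Ago2 at 1.38 ± 1.24 (1.99 against GV7 to GV9) and Ago1 at −2.52 ± 2.17. Ago1 was at 43.7 CPM in GV1 and 63.1 CPM in GV2, and its ratio was −1.90 without GV2, −0.95 without GV1 and GV2, −3.30 without MII1 and −1.80 against GV7 to GV9.

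Genes of fertilization and egg activation had a median of −0.10 ± 0.35 over 15 genes (percentile 17.8), with 11 within 2-fold. It had no fixed sign, with 0.06 without GV3, 0.00 without GV5, 0.08 without MII6, 0.12 against GV7 to GV9 and 0.25 with medians over oocytes. The relative level of this list per oocyte was higher in MII, with means of 1.70 in GV and 2.20 in MII. Izumo1r, which encodes the sperm receptor Juno, was at 377 and 588 CPM (1.63 ± 1.29; 0.99 without MII5 and MII6). Wee2, an oocyte kinase that inhibits CDK1, was at 798 and 273 CPM (−0.57 ± 0.55), and the calcium sensor gene Stim1 had a ratio of −2.88 ± 2.11. Stim1 was at 35.8 CPM in GV1 and 41.3 CPM in GV2, and its ratio was −2.28 without GV2, −0.88 without GV1 and GV2 and −1.23 against GV7 to GV9. Cytoskeleton and spindle genes had a median of −0.14 ± 0.44 over 20 genes (percentile 2.73). Tubb6 was at 767 and 750 CPM (0.95 ± 1.04; 0.64 without the feature), the actin nucleator gene Spire2 at 1.12 ± 1.09 (2.53 against GV7 to GV9) and Tuba1a at −3.31 ± 1.91 (−3.90 without MII4, −2.50 against GV1 to GV6, −4.56 against GV7 to GV9). Proteasome subunits had a median of −0.25 ± 0.81 over 31 genes (percentile 5.91), in which Psmd4 was at 367 and 570 CPM (1.62 ± 0.80; 2.57 against GV7 to GV9) and Psmd13 had 334 counts in GV and 1 in MII (in MII4), 73.3-fold lower in CPM (13.1 to 2903), and 16.5-fold (2.63 to 683) against GV7 to GV9. Cohesin and chromosome axis genes had a median of 0.21 ± 1.25 over 6 genes (percentile 68.0; mean −0.01), −0.02 without MII1, −0.31 without MII2 and −0.06 against GV7 to GV9. It was lower in MII on the scale of total counts and without the feature (−0.10), but higher with TMM (0.098). Syce2 was at 499 and 468 CPM (0.89 ± 1.19; 0.58 without the feature by total counts, 1.52 against GV7 to GV9, 0.19 without MII5 and MII6) and Smc1b at −1.02 ± 1.33 (−1.68 without MII1).

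Genes of DNA methylation and imprint maintenance had a median of 0.27 ± 0.47 over 10 genes (percentile 51.2), and 9 of the 10 lay within 2-fold. It was lower in MII on the scale of total counts and without the feature (−0.042), but higher with TMM (0.16). The maintenance methyltransferase gene Dnmt1 was at 6967 and 2444 CPM (−0.53 ± 0.81). Dppa3, which protects the maternal genome from demethylation, was at 198 and 50.8 CPM (−0.98 ± 1.43), and the imprint-binding factor gene Zfp57 at 3141 and 3937 CPM (1.31 ± 0.88; 0.69 against GV7 to GV9). Of 14 genes of zygotic genome activation 2 were measured: Sp110 at 381 and 81.2 CPM (−1.25 ± 0.74; −1.90 against GV7 to GV9) and Tcstv1 at 11.4 and 3.74 CPM (−0.61 ± 1.58; 0.14 without GV4). Their list median was −0.93 (percentile 9.12), and 0.33 with no filter on level. Of 10 nuclear and small noncoding RNAs 2 were measured, with a list median of −0.25 (percentile 58.9), which was 0.11 without GV1, 0.07 without GV1 and GV2 and 0.01 without MII3, but −1.0 against GV1 to GV6, −0.58 without MII4 and −0.51 without MII5 and MII6. Malat1 was at −0.77 ± 1.89 (0.04 against GV7 to GV9, −0.13 without GV1, −1.71 without MII5 and MII6) and Meg3 at 0.28 ± 1.30 (1.38 against GV7 to GV9, −0.53 without MII4).

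Markers of cumulus and granulosa cells, the somatic cells around the oocyte, were present at low levels in GV. They took 95.8 CPM of the summed GV counts (95% interval 92.9 to 98.7) and 17.1 CPM in MII (14.6 to 20.0). The share was 14.4 to 290 CPM over the GV oocytes and highest in GV1, and 3.71 to 24.3 CPM over the MII oocytes. Of 18 markers 4 were measured, with a median ratio of −5.83 ± 1.66, or −4.54 with genes at 0 in MII set to their bound, and −1.97 against GV7 to GV9. Inha, named above among the lowest ratios, is one of them. The gap was smaller in relative levels per oocyte, the measure behind the spread. There the list averaged −2.06 in GV (−3.85 to 0.07) and −3.84 in MII (−4.33 to −3.34). Theca and stroma markers took 6.01 CPM in GV (5.31 to 6.78) and 4.67 CPM in MII (3.41 to 6.25), with Col1a1 highest at 2.98 and 4.26 CPM. Without MII5 the MII share was 0.626 CPM, and without GV2 the GV share was 3.73 CPM. Oviduct epithelium markers took 2.60 CPM in GV and 0.104 CPM in MII, with Pax8 at 1.48 CPM in GV and 0 counts in MII, and the GV share was 1.64 CPM without GV2. Blood and immune markers took 0.342 CPM in GV and 0.104 CPM in MII, and the most abundant, Alas2, had 13 counts in GV. The GV share of this list was 0.184 CPM without GV5.

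More genes were detected per GV oocyte. After thinning every oocyte to 808641 counts, GV oocytes had a median of 13472 genes with at least 1 count (12401 to 15197), and MII oocytes had 11034 (8830 to 12516), so that the ranges overlapped. From all counts the medians were 17013 and 11622. With the feature left out and 536101 counts per oocyte they were 12627 and 11308. The mitochondrially encoded share of counts had a median of 0.923% in GV (0.258% to 4.69%) and 0.400% in MII (0.0953% to 1.12%), and without the feature 0.956% and 0.725%. The GV median depended on the set, at 1.52% in GV1 to GV6 and 0.616% in GV7 to GV9. Without the feature it was 0.693% in GV7 to GV9, below the MII median. With the feature counted, the MII median was 0.657% without MII5 and MII6.

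Over all pairs, oocytes of different stages were nearly as alike as oocytes of 1 stage, but oocytes of some subsets were more alike than that. Spearman's rho across measured genes had a median of 0.77 within GV (36 pairs, 0.65 to 0.92), 0.79 within MII (15 pairs, 0.70 to 0.91) and 0.75 between GV and MII (54 pairs, 0.53 to 0.87). These are correlations across genes, which are not independent replicates. Within GV, rho was 0.79 among GV1 to GV6, 0.90 among GV7 to GV9 and 0.74 between these sets, and each set had a median of 0.75 with MII. Without MII5 and MII6 the median was 0.88 within MII and 0.78 between GV and MII. The coefficient of variation between oocytes, over 2481 genes of at least 50 CPM in both stages, had a median of 0.417 in GV and 0.503 in MII. It was 0.260 among GV7 to GV9, and 0.286 in MII without MII5 and MII6.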

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

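Of the tests below, the 2 on the unnamed feature and the 2 on RNA of follicle cells in the GV samples were chosen after the result was seen. In 233 groups of oocytes 18 single oocytes stood far from the others of their stage: 2 among 15 groups of whole-oocyte measures, 0 among 46 of gene lists and 16 among 172 of named genes. In 7 of these groups 1 oocyte held all the counts, which fixes the outcome, and in 10 all oocytes were at 0. The other 216 groups gave 11, against 10.8 at 1 in 20 groups. The groups share the same oocytes and some repeat a measure, so these numbers cannot show whether the 11 arose by chance. Most of the 11 fell on 2 oocytes, GV2 and MII5.

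The mitochondrially encoded share of GV2 was 4.69%, with the next highest GV oocyte at 1.88%, and it was also 4.69% with the unnamed feature left out. In log2(CPM + 1), GV2 was lowest of the GV oocytes for Rps2 (7.05, next 8.61) and for Izumo1r (6.08, next 7.84). MII5 was highest of the MII oocytes for Nfu1 (10.12, next 8.97), Izumo1r (10.10, next 9.08) and Col1a1 (4.66, next 0.79), and lowest for Ythdf2 (1.15, next 2.79) and for Sohlh2, at 0 with the next at 4.75. MII2 was lowest for Apol6 (0.73, next 4.03) and MII6 for Sp110 (5.55, next 6.39). In 7 genes a single MII oocyte held all the MII counts and the others were at 0. These were Dclk1 and Cplx2 (both 0.79 in MII3), Zeb2 and Tut4 (both 0.73 in MII2), Eef1g (1.80 in MII1), Ndufc1 (1.16 in MII1) and Psmd13 (0.60 in MII4), all of 1 or 2 counts.

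The unnamed feature had 0 counts in each of GV1 to GV6 and took at least 3.43% of every other library. Too few counts are argued against, since the shallowest of GV1 to GV6 would have held 146393 counts at the lowest share of GV7 to GV9. The M21 annotation used here for names is argued against as the one behind these files, since each of GV1 to GV6 held at least 103 gene IDs that it lacks. Another annotation without the feature, its removal from the files and its depletion from the libraries all stay open, and none was tested. No biological explanation was tested, since the labels put all 9 oocytes in 1 stage.

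Ribosomal protein mRNAs and nuclear-encoded mRNAs of oxidative phosphorylation were lower in MII, at −1.37 and −0.96 relative to the median gene. Poorer recovery of short transcripts in MII is argued against for both, since both medians lay at percentile 0 of random lists matched on level and transcript length. A pattern made by 1 of the 2 sets of GV files stays open: the medians nearest to 0 were −0.90 and −0.76, below the bound of −0.5 set beforehand, but by less than the spreads between oocytes of 1.05 and 1.07. Against GV7 and GV9, the 2 GV oocytes with a cumulus marker share no higher than the highest in MII, the medians were −1.71 and −0.80. That highest share, 24.3 CPM in MII6, counts the unnamed feature, which took 61.2% of MII6. With the feature left out the cut would be higher. GV4 (53.5 CPM) and GV5 (59.7 CPM), with 0 counts of the feature, would then also pass, and so would GV8 (41.5 CPM with the feature counted). Medians against such a wider group were not taken. RNA of follicle cells stays open for both lists. The rule of this test asked for oocytes of both sets of GV files. GV7 and GV9 come from 1 set, against which the ribosomal protein median was already −2.11. The oxidative phosphorylation median also lay below −0.5 by less than its spread. In addition, the cut depends on the feature. Stage, an untested candidate explanation, cannot be told apart from mouse, collection or file processing, since all MII files share a header that no GV file has.

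At equal totals more genes were detected in GV1 and GV2 (15197 and 14199) than in any other GV oocyte (up to 14026). A broad background of reads from genes that oocytes do not use stays open: the lower of the numbers of olfactory receptor genes in these oocytes differed from the highest other GV oocyte by −7, which met the outcome set beforehand against it but lies within the counting spread of 9.95. That highest oocyte was GV9 (53), of the other set of files. Within their own set GV1 and GV2 held 50 and 46 such genes, and GV3 to GV6 at most 37. RNA of follicle cells alone is argued against, since GV1 and GV2 held 20 and 21 of 40 genes restricted to other organs, at least 13 more than any other GV oocyte. No biological explanation was tested, since the labels set these oocytes apart in no way.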

How the results depend on the processing

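Settings that use totals without the feature, ratios relative to the median gene, parts of the GV oocytes, or that leave out 2 oocytes were chosen after seeing the data. Where no cause is named below, the cause was not tested. Relative to the median gene, where scaling has no effect, 11 of 23 list medians had the same sign in every alternative: zona and secreted factors, subcortical maternal complex, DNA methylation, meiotic cell cycle, ribosomal proteins, oxidative phosphorylation, proteasome, RNA polymerase II, cytoskeleton, histones and cumulus markers. The other 12 had another sign in at least 1, mostly within the spread between oocytes. Beyond that spread, 4 of 573 list values reversed and 5 moved, and of 1825 values of 83 named genes 7 reversed and 24 moved. Of these genes 68 had the same relative sign throughout. Scaling can still turn the unadjusted ratio: DNA methylation and 6 of the 68 genes (Dcp1a, Btg4, Syce2, Eef2, Dicer1 and Tubb6) were above the median gene but lower in MII by total counts. Depth limits MII most: 3 counts were 1.28 to 3.71 CPM in an MII oocyte and 0.422 to 0.814 CPM in a GV oocyte. No paired analysis was possible because the numbers of GV and MII oocytes name different cells and the results come from no test. Ratios relative to the median gene are by construction the same under every scaling, and against GV7 to GV9 the noncoding list and H2bc7 (0 counts in both) gave no value.

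Genes at least 4-fold lower in MII (1529) numbered 716 with TMM, 688 with median-of-ratios, 825 without the 50 top genes, 830 without the feature and 657 relative to the median gene. Genes at least 4-fold higher (51) numbered 161, 180, 125, 122 and 198 in that order, 202 with medians over oocytes and 292 against GV7 to GV9. At 1 CPM, 20 CPM and no filter, which change the genes counted, lower genes numbered 3746, 443 and 6343 and higher genes 240, 25 and 2050. Relative to the median gene, lower genes (657) numbered 2033, 111 and 3667 with these filters and 423 without GV1 and GV2. Higher genes (198) numbered 669, 84 and 2700, 332 with medians over oocytes and 675 against GV7 to GV9. The median of all measured genes (−0.98) was −0.11 with TMM, −0.063 with median-of-ratios, −0.31 without the 50 top genes and −0.31 without the feature. Leaving out each oocyte in turn gave 1297 to 1862 lower and 45 to 74 higher genes, 517 to 786 and 152 to 266 relative to the median gene, and a median of −1.11 to −0.82. The list median ran from −1.75 to −1.07 for ribosomal proteins and from −1.20 to −0.74 for oxidative phosphorylation. It ran from −0.99 to −0.73 for zona and secreted factors, −0.94 to −0.55 for the subcortical maternal complex and −0.64 to 0.98 for mitochondrially encoded mRNAs, highest without GV2.

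Against GV7 to GV9 the relative list median was 1.48 for oocyte transcription factors, −1.65 for the subcortical maternal complex and 2.01 for mitochondrially encoded mRNAs. On the scale of total counts the first and last were 0.62 and 1.15. It was 0.25 for fertilization genes with medians over oocytes and 0.33 for zygotic genome activation genes with no filter. For cumulus markers it was −3.97 with medians over oocytes, −8.71 at 20 CPM, −2.27 with no filter and −1.97 against GV7 to GV9. Lists below 0 by total counts were above it relative to the median gene for DNA methylation (0.27), dormant mRNAs (0.26), cohesin (0.21), decay (0.041) and glycolysis (0.10; 0.036 with median-of-ratios), by construction of the scaling. Agbl2 was at 0.049 against GV1 to GV6. Against GV7 to GV9, Zp3 was at 0.19, Obox2 1.75, mt-Nd2 2.18, mt-Nd4 1.03, Polr2c 0.88 and H1f1 1.47. Genes detected at 5 counts or more were 8919 in GV and 7384.5 in MII, and 17013 in GV without thinning. The cumulus share in MII was 27.8 CPM without the feature. Median rho was 0.90 among GV7 to GV9 and 0.88 in MII without MII5 and MII6, with coefficients of variation of 0.26 and 0.29.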

Other observations

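The comparison of GV1 to GV6 with GV7 to GV9 and the genes named from it were chosen after seeing the data; the test of the sequence element was not. The genes are the 6 furthest apart in each direction among protein-coding genes of at least 20 CPM whose ranges in the 2 sets did not overlap. Of 10763 genes measured, 922 were at least 4-fold lower and 603 at least 4-fold higher in GV7 to GV9, relative to the median gene. Tox3, a high mobility group box factor, was at 68.3 to 113 CPM in GV1 to GV6, had 0 counts in GV7 to GV9, and was at 10.9 to 48.2 CPM in MII. Sh3rf2 was at 43.4 to 173 CPM in GV1 to GV6, 0 to 0.471 CPM in GV7 to GV9 and 55.6 to 129 CPM in MII. Myo7a, Bcl11a, Arhgap23 and Maf were at 36.7, 38.3, 23.2 and 20.0 CPM in the summed counts of GV1 to GV6 and at 0 in GV7 to GV9. In the other direction Tceal8 had 0 counts in GV1 to GV6 and 15.3 to 45.7 CPM in GV7 to GV9. Pxdn was at 0.559 and 194 CPM, Btn1a1 at 0.528 and 127 CPM, Pnpla3, a lipid droplet protein, at 0.217 and 72.8 CPM, Zfp990 at 0.124 and 33.4 CPM and Agbl2 at 1.68 and 217 CPM. Tox3 and Sh3rf2 were thus present in every MII oocyte, and Pxdn in none.

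Cytoplasmic polyadenylation elements near the 3′ end mark mRNAs that are translated during maturation. The hypothesis was that mRNAs with such an element keep a higher relative level in MII. Genes with TTTTAT or TTTTAAT in the last 100 nt of the 3′ UTR of their annotated transcript were compared with random lists matched on level and transcript length, with 97.8% of measured protein-coding genes searched. Against GV1 to GV6 the median of 1765 genes was −0.02, at percentile 20.6 (central 95% of random lists −0.04 to 0.05). Against GV7 to GV9 the median of 1697 genes was −0.08, at percentile 0 (−0.01 to 0.11). The hypothesis was not borne out, since neither median lay above the random lists, and the lower percentile was 0. By transcript length, the median relative ratio was 0.07, 0.07, 0.04, −0.00 and −0.14 from the shortest to the longest of 5 equal groups of genes.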
